A study of Danio rerio with 10 samples.

How the data were processed

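RNA from zebrafish (Danio rerio) was sequenced in 10 libraries that the labels describe as brain at an age of 90 days. The groups were taken from the sample titles: 1 library of WT fish and 3 each of NF1-KO, RB1;TP53-cKO and NF1;TP53-cKO fish, where KO stands for knockout and cKO, in its usual sense, for conditional knockout. The series description speaks of sequencing in triplicate on an Illumina GAIIx, but the samples hold 1 WT library. The column of the WT library carried the name of the AB strain, as in that sample's description, and the mutant columns carried the numbers 1 to 9, which were matched to the numbers in the sample descriptions. All 10 libraries had a column and 0 columns were left over.

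The deposited table gives, per the file headers, a count and an FPKM (fragments per kilobase of gene, scaled by library size) for each of 32105 Ensembl genes in each library. The deposited counts are whole numbers with no normalization. The deposited FPKM values equal the counts divided by 1 length per gene and by the library's summed count. This was checked on the 18306 genes with 10 or more counts in every library, where the implied length differed between libraries by at most 0.0089%. Per the submitters' processing notes, CASAVA 1.8, HISAT2 2.0.4 and StringTie 1.3.0 were used with the genome build GRCz10. The annotation release, strand setting and read length were not stated. No 2 library columns were identical, and no 2 libraries of a group were as close as resampling of 1 library would make them (lowest chi-square per degree of freedom 20.2). Gene symbols came from the table and from a table of gene names, in which 26269 of the Ensembl identifiers had a symbol. Coordinates are those of the deposited table.

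The summed counts ran from 18166309 to 27373861 per library. A count of 0 therefore allowed up to 3 counts, or 0.110 to 0.165 CPM (counts scaled to library size). Such floors cover counting error only, because reads without molecular identifiers are not independent molecules.

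The test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the counts, with genes kept by filterByExpr (22984 genes), TMM factors (0.938 to 1.06), and 1 fit of the 4 groups over all 10 libraries with 6 residual degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Since WT has 1 library, that library is assumed to vary like the others. There were 7 pairwise comparisons: the mean of the mutant groups with WT, each mutant group with WT, and the mutant groups with each other. An F test over the mutant groups asked for any difference among them. Log2 fold changes are given with their standard error. Levels are given as FPKM, as mean ± SD where a group has 3 libraries. The common biological coefficient of variation was 0.491.

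Gene lists were fixed by symbol: 36 lists with 968 entries, of which 934 were found in the table. They cover pathways, cell types of the brain and tissues near it, and the targeted genes. The 35 lists other than the targeted genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera compares a list with all other tested genes. The test was repeated with the correlation estimated from the data. Camera makes a call at an adjusted p under 0.05. For each list, members were also counted at an adjusted p under 0.05 adjusted over the list alone. A further 7 lists were added after the data had been seen and are reported only as levels, as the mean of log2(FPKM + 1) over their members.

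The genes named follow a rule: the targeted genes, for each list described the 2 to 4 members with the smallest p, and the genes that passed with the largest fold change. Where fewer than 5 genes passed, which held for every comparison, the rule names instead the 5 genes with the smallest p in each direction that have a symbol other than a clone or locus name and a mean of at least 1 FPKM, and they are said not to pass. These genes also needed every library of one side above every library of the other, so that separation is no evidence of its own. A gene said to have the smallest p of a comparison is the smallest among such genes. Other genes are said to be chosen after their values were seen.

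The groups, the tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined. That choice covered both units, limma on log2(FPKM + 1) for FPKM alone and edgeR for counts, and the counts were used. The alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, quantile normalization, library weights (voomWithQualityWeights of limma), limma on log2(FPKM + 0.1), no filter, a mean of at least 2 FPKM, a minimum absolute log2 fold change of 1, the 2 compared groups alone, the replicate number as a block, leaving out each mutant library in turn, and an adjusted p of 0.1 for overlaps. Further alternatives, chosen after seeing the data, were limma on log2(FPKM + 1) with a mean of at least 0.5 FPKM, leaving out 3 libraries that lay apart, and leaving out 2 libraries high in pancreatic enzymes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

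The test was tested on simulated data with the trended dispersions of these libraries and 50 changed genes at each fold among 22984. The changed genes were drawn from those with an average log2 CPM over 1, so recovery of weaker genes was not tested. For NF1;TP53-cKO versus RB1;TP53-cKO it recovered 8% of the genes at a fold of 2, 56% at 4, 98% at 16 and 100% at 64, with 8 calls among unchanged genes. For the mutants versus WT it recovered 0%, 12%, 92% and 100%, with 4 such calls. Camera called the 1 list that was shifted in simulated data, and 1 of the random lists reached an unadjusted p under 0.05. The simulated genes were drawn independently of each other, so this does not test the preset correlation or the p of correlated lists.

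Raw reads, isoforms, sequence variants and the knockout alleles were not analysed here. For the adult globins, the symbols in the table overlap on chromosome 3, so that reads could be lost between them, and their counts near 0 are not read as absence.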

Results

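RNA of zebrafish labelled as brain was sequenced from WT fish (1 library) and from NF1-KO, RB1;TP53-cKO and NF1;TP53-cKO fish (3 libraries each). Their genotypes remove tumor suppressors: NF1 encodes neurofibromin, which turns off Ras, RB1 restrains the E2F factors that drive DNA replication, and TP53 encodes the p53 transcription factor. The series sets wild type fish against glioma, so the comparisons ask how these genotypes differ from WT and from each other. The summed counts were 19316291 for WT, 23118599, 21153971 and 26431887 for replicates 1, 2 and 3 of NF1-KO, 27373861, 25435784 and 23705920 for those of RB1;TP53-cKO, and 20600832, 20250939 and 18166309 for those of NF1;TP53-cKO. Between 23991 and 24928 genes had a count in a library, and 22984 were tested. No label says whether the replicates are separate animals, so each p measures only the spread between these libraries.

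The targeted genes were expressed in every group, and none of them passed the test in any comparison. A knockout may leave the transcript in place. The level of nf1a (ENSDARG00000012982, chromosome 15, 30980906 to 31104063 on GRCz10) was 5.10 FPKM in WT, 4.74 ± 0.341 in NF1-KO, 4.13 ± 0.943 in RB1;TP53-cKO and 4.16 ± 0.101 in NF1;TP53-cKO (mean ± SD, n = 3 per mutant group, in this order below). For nf1b (ENSDARG00000004184, chromosome 10, 37324870 to 37455267) the levels were 4.04 in WT, then 3.61 ± 0.377, 2.88 ± 1.69 and 2.82 ± 0.228. The wide spread of the second mutant group came from its replicate 3, with 0.929 FPKM. For rb1 (ENSDARG00000006782, chromosome 21, 22924130 to 22980873) they were 6.81, then 8.56 ± 2.14, 11.8 ± 2.78 and 10.6 ± 3.37. For tp53 (ENSDARG00000035559, chromosome 5, 23582427 to 23594005) they were 11.9, then 15.4 ± 1.31, 20.9 ± 4.44 and 29.3 ± 11.5. In NF1-KO the log2 fold changes against WT were -0.09 ± 0.26 for nf1a and -0.15 ± 0.59 for nf1b (edgeR adjusted p = 1 for both). In RB1;TP53-cKO they were 0.85 ± 0.49 for rb1 and 0.87 ± 0.50 for tp53 (edgeR adjusted p = 0.859 for both). In NF1;TP53-cKO they were -0.19 ± 0.26 for nf1a, -0.42 ± 0.58 for nf1b and 1.41 ± 0.52 for tp53 (edgeR adjusted p = 0.747, 0.753 and 0.595). Between NF1;TP53-cKO and NF1-KO the difference in tp53 was 1.03 ± 0.34 (edgeR adjusted p = 0.401), and without NF1;TP53-cKO replicate 3 it was 1.33, with an adjusted p = 0.0247.

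**Figure D1:**
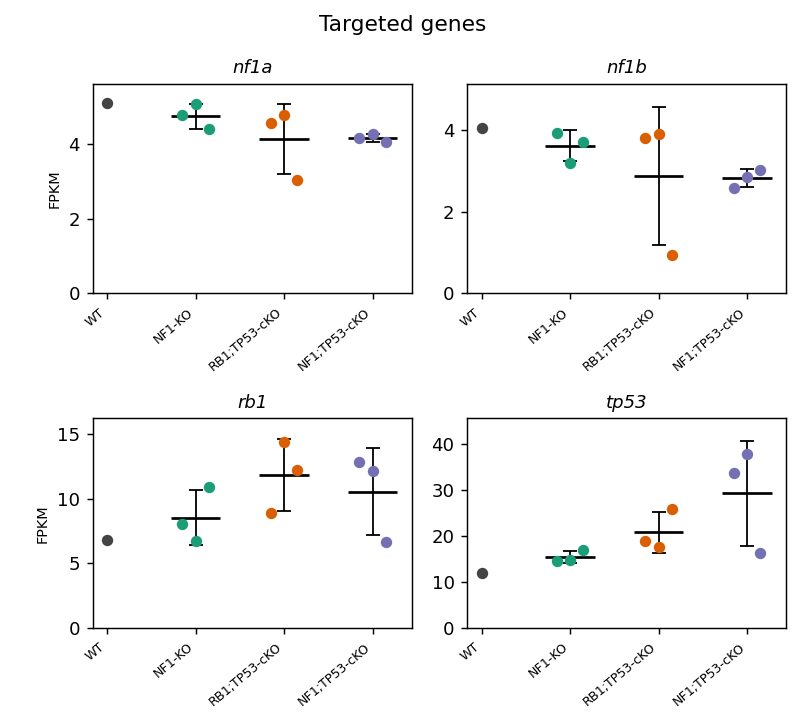
FPKM of the targeted genes nf1a, nf1b, rb1 and tp53 in each library (points), by group, with bars at the mean and error bars of 1 SD where a group has 3 libraries. For tp53 the group means run from 11.9 FPKM in WT to 29.3 FPKM in NF1;TP53-cKO, where replicates 1 and 2 lie at 33.9 and 37.9 FPKM and replicate 3 at 16.3 FPKM.

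The libraries did not sort by genotype. On the first dimension of the multidimensional scaling plot, which held 56.8% of the variation over 1000 genes (16.5% on the second), RB1;TP53-cKO replicate 3 and NF1;TP53-cKO replicates 1 and 2 lay apart from the other 7. Of the 9 mutant libraries, 2 were closest to one of their own group, namely NF1;TP53-cKO replicates 1 and 2. The genes that follow were chosen after their values were seen. The hatching enzyme gene he1a, which is active in the hatching gland of embryos, stood at 87.9, 263.5 and 73.7 FPKM in the 3 libraries that lay apart and at 1.25 FPKM or less elsewhere. The embryonic globin gene hbbe3 stood at 508.6, 1100 and 1062 FPKM in them and at 28.5 FPKM or less elsewhere. The rod opsin gene rho stood at 6.46, 5.18 and 3.05 FPKM against 253 to 1180 FPKM, and the ultraviolet cone opsin gene opn1sw1 at 1.38, 0.792 and 0.778 FPKM against 167 to 1378 FPKM. Myelin basic protein transcripts (mbpa) stood at 0.0976, 0.129 and 0.0572 FPKM against 1.32 to 9.82 FPKM. The heat shock gene hsp70l was at 469.6 and 503 FPKM in NF1;TP53-cKO replicates 1 and 2 and at 5.26 to 21.5 FPKM elsewhere. Pancreatic elastase (ela2) reached 278 FPKM in NF1-KO replicate 3 and 849 FPKM in RB1;TP53-cKO replicate 2. Markers of tissues other than brain were high in all 10 libraries: the skeletal muscle list took 6.32% to 8.77% of the counts and the epidermis list up to 2.04%.

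**Figure D2:**
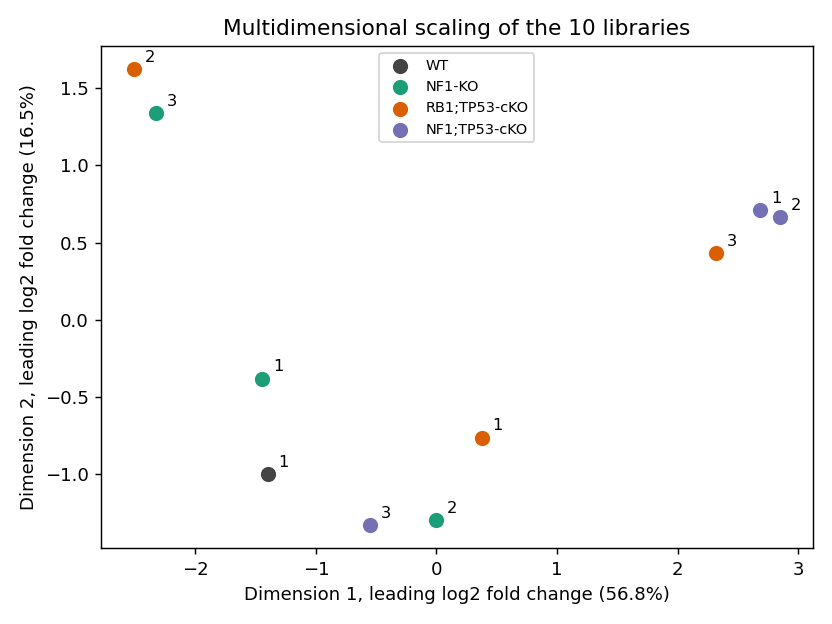
Multidimensional scaling of the 10 libraries on the 1000 genes that differ most, colored by group, with the replicate number beside each point. RB1;TP53-cKO replicate 3 and NF1;TP53-cKO replicates 1 and 2 lie apart from the other 7 libraries on dimension 1, which holds 56.8% of the variation.

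**Figure D3:**
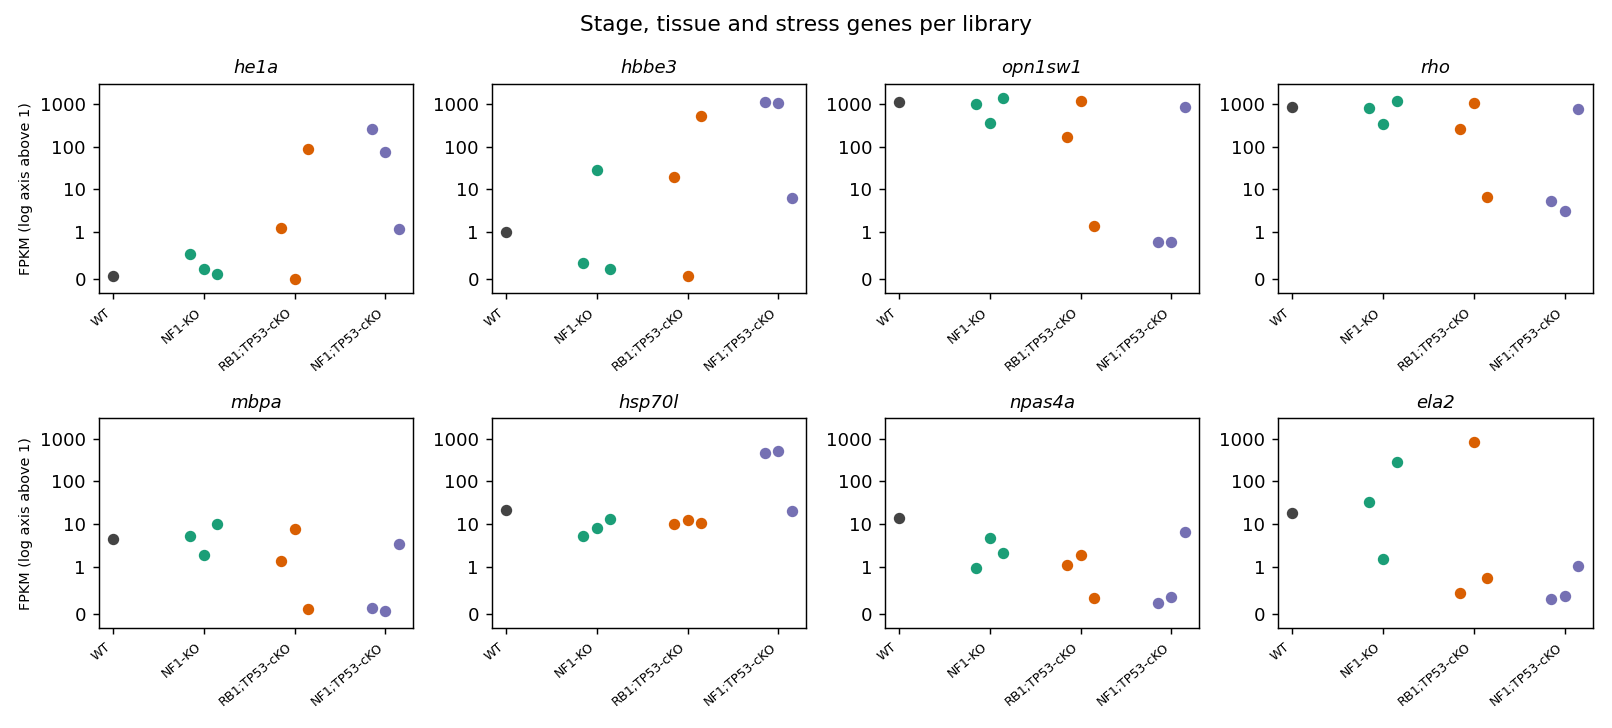
FPKM of 8 marker genes in each library, on a symmetric log axis (linear near 0), colored by group. The hatching enzyme he1a and the embryonic globin hbbe3 are high, and the opsins opn1sw1 and rho and myelin basic protein mbpa low, in RB1;TP53-cKO replicate 3 and NF1;TP53-cKO replicates 1 and 2, while hsp70l is above 469 FPKM in the latter 2 libraries.

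**Figure D4:**
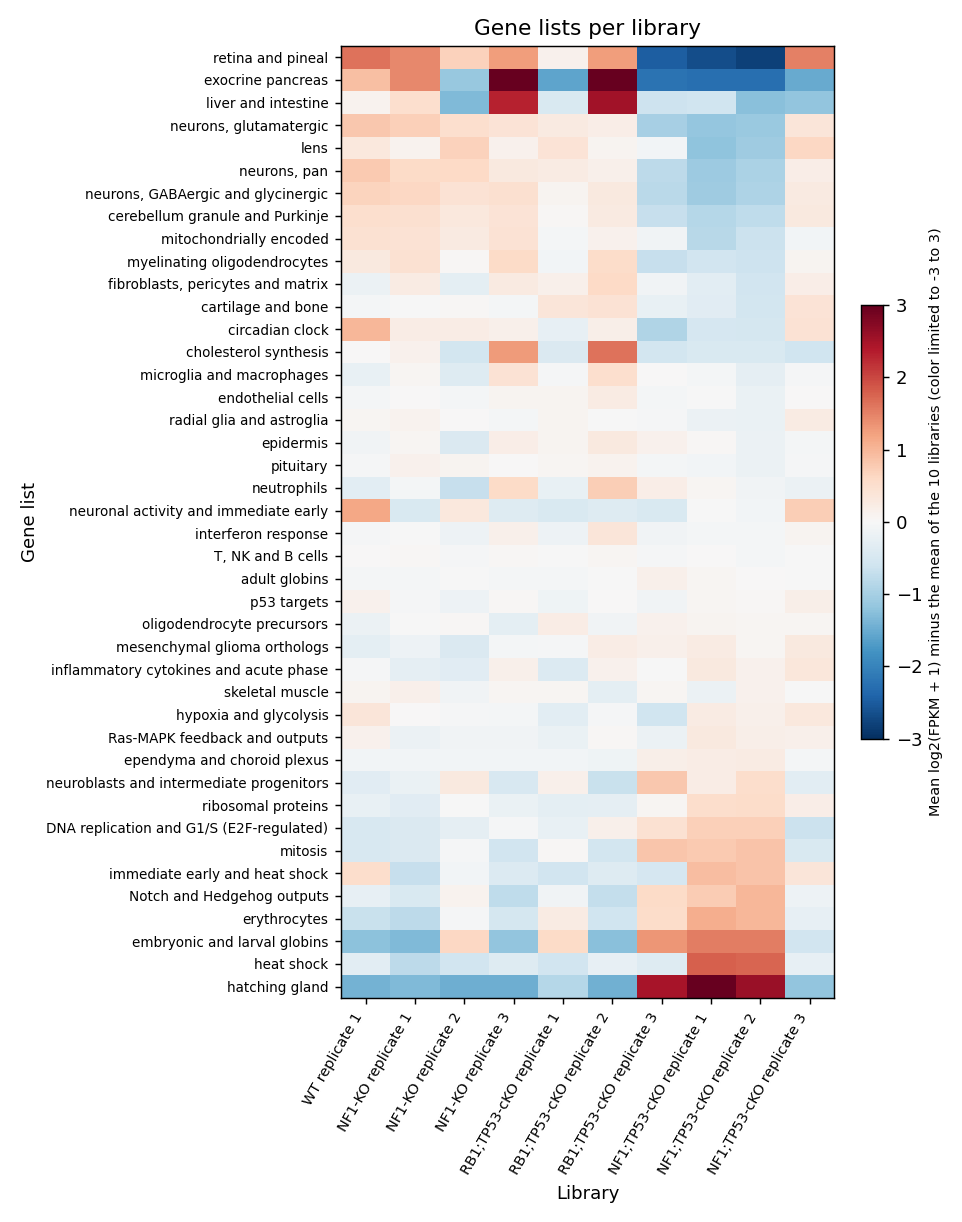
Mean log2(FPKM + 1) of each gene list in each library, minus the mean over the 10 libraries, with the color limited to -3 to 3. The retina and pineal list runs from 1.01 to 1.34 in the 3 libraries that lie apart and from 3.95 to 5.46 in the other 7.

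The comparison of the mutants with WT asks what the glioma genotypes share. Genes of the circadian clock were lower in the mutants: 27 of 35 measured members had a negative log2 fold change, the mean was -1.10, and 8 fell when adjusted over the list alone (camera adjusted p = 1.08e-17, and adjusted p = 0.289 with an estimated correlation). Among them were the clock repressor genes ciartb, at -1.61 ± 0.35, and cry2, at -1.15 ± 0.28, and the clock output factor dbpb, at -3.11 ± 0.78. All 28 members of the list of neurons, pan, had negative values, with a mean of -0.76 (camera adjusted p = 1.25e-10, and adjusted p = 0.504 with an estimated correlation). The synaptic vesicle fusion gene snap25a was at -1.37 ± 0.43 and the neurofilament gene nefmb at -0.81 ± 0.26. Of the retina and pineal list, 31 of 32 members were lower, with a mean of -1.09 (camera adjusted p = 1.65e-07, and adjusted p = 0.592 with an estimated correlation). Proliferation genes were higher, namely 25 of 25 members of the DNA replication and G1/S list, with a mean of 0.74 (camera adjusted p = 2.17e-06, and adjusted p = 0.592 with an estimated correlation), and 26 of 26 of the mitosis list, with a mean of 0.76 (camera adjusted p = 6.6e-06, and adjusted p = 0.629 with an estimated correlation). The neuron, retina and proliferation groups moved with the 3 libraries that lay apart, where the list of neurons stood at 3.89, 3.60 and 3.73 as mean log2(FPKM + 1), against 4.84 to 5.47 elsewhere, and the mitosis list at 4.75, 4.70 and 4.76, against 3.35 to 3.95. The circadian clock list stood at 3.90 in the single WT library and at 2.01 to 3.35 in the mutant libraries. It was lowest in the 3 that lay apart, but stood at 3.05 to 3.13 in NF1-KO, which holds none of them. Its fall against WT therefore rests on the single WT library.

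No gene passed in edgeR for the mutants versus WT (smallest adjusted p = 0.325), while 567 genes reached an unadjusted p under 0.05 (328 higher and 239 lower). That is 2.47% of those tested, fewer than unchanged genes would give by chance. DESeq2 called 7 genes, library weights in limma 29, and limma on log2(FPKM + 1) 1. Without NF1;TP53-cKO replicate 3, the unadjusted count was 2638. The 5 genes with the smallest p in each direction, none of which passed, included the kinase gene prkg1a (ENSDARG00000020656, chromosome 13, 40689122 to 40833599), at 0.871 FPKM in WT and 2.51 ± 0.173, 2.97 ± 0.758 and 3.45 ± 0.207 FPKM in the mutant groups, and higher in 9 of 9 mutant libraries, at 1.82 ± 0.36. The p53 inhibitor gene mdm4 (ENSDARG00000057513, chromosome 11, 22637980 to 22663624) was at 4.69 FPKM in WT and 9.30 ± 1.11, 8.04 ± 1.17 and 9.92 ± 0.300 FPKM in the mutants, at 1.00 ± 0.25. On the lower side, the antiproliferative gene tob1b (ENSDARG00000021372, chromosome 12, 841246 to 844516) was at 95.6 FPKM in WT and 43.7 ± 3.61, 32.4 ± 3.63 and 58.6 ± 7.76 FPKM in the mutants, at -1.08 ± 0.19 and lower in 9 of 9 libraries. For prkg1a and tob1b the 9 of 9 follows from the rule for named genes, which requires it. The cell cycle inhibitor cdkn1a (ENSDARG00000076554, chromosome 22, 565659 to 570089), a p53 target, was at 16.3 FPKM in WT and 3.37 ± 1.09, 2.56 ± 1.13 and 5.23 ± 1.60 FPKM in the mutants. Its log2 fold change was -2.14 ± 0.43, and it fell when adjusted over the p53 targets list alone (edgeR adjusted p = 0.0171). That list as a whole was not called by camera (adjusted p = 0.677), and its mean of -0.06 and median of 0.19 differed in sign. The gene si:dkey-84j12.1 (ENSDARG00000094625, chromosome 5, 43464611 to 43591162), chosen after its values were seen, was at 4.47 FPKM in WT and at 0.0357 to 0.309 FPKM in the 9 mutant libraries, at -5.04 ± 0.58 (edgeR adjusted p = 0.325). It was the gene called by limma on log2(FPKM + 1). A second entry of the same name (ENSDARG00000075126) overlaps it, at 6.04 FPKM in WT and 1.68 to 7.65 FPKM in the mutants, so the division of reads between the entries is uncertain.

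NF1-KO versus WT asks what loss of the Ras regulator does alone. The immediate early and heat shock list was lower, with negative values for 25 of 31 members and a mean of -1.02 (camera adjusted p = 1.96e-22, and adjusted p = 0.0168 with an estimated correlation). The activity-induced transcription factor genes ier2, junbb and nr4a1 were at -1.74 ± 0.43, -1.80 ± 0.54 and -1.58 ± 0.60. Among the 10 calls that camera made here, this was the one that held with an estimated correlation. It rests on the single WT library: of the lists added after the data were seen, the neuronal activity and immediate early list stood at 4.07 as mean log2(FPKM + 1) in WT and at 2.44 to 3.64 in the 9 mutant libraries, and the heat shock list at 4.07 in WT and 3.58 to 3.99 in NF1-KO. The circadian clock list had a mean of -0.80, with 26 of 35 members lower (camera adjusted p = 4.08e-16, and adjusted p = 0.278 with an estimated correlation). This fall rests on the WT library too, at 3.90 as mean log2(FPKM + 1) against 3.05 to 3.13 in NF1-KO. The hypoxia and glycolysis list had a mean of -0.41, with 21 of 25 lower (camera adjusted p = 4.89e-06, and adjusted p = 0.272 with an estimated correlation), and its member ddit4, an inhibitor of mTOR signaling, was at -1.98 ± 0.60. Camera placed the Ras-MAPK feedback and outputs list lower, although its members were evenly divided, with 11 positive, 12 negative and a median of -0.09 (camera adjusted p = 0.000517, and adjusted p = 0.272 with an estimated correlation). Its member mych, a Myc family gene, fell, at -1.45 ± 0.32, when adjusted over the list alone (edgeR adjusted p = 0.0374), and dusp5 and dusp4, phosphatases that act back on MAP kinases, were at -1.0 ± 0.31 and -0.85 ± 0.41.

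Immune and proliferation genes of this comparison depended on single libraries. The microglia and macrophages list was higher, with 29 of 38 members positive and a mean of 0.60 (camera adjusted p = 0.00856, and adjusted p = 0.918 with an estimated correlation), and so was the neutrophils list, with 16 of 17 and 0.77 (camera adjusted p = 0.00611, and adjusted p = 0.918 with an estimated correlation). Without NF1-KO replicate 3, the library of the group with the most pancreatic transcripts (0.356% of its counts), these values were adjusted p = 0.619 and 0.794. The DNA replication and G1/S (E2F-regulated) list was higher in 23 of 25 members, with a mean of 0.30 (camera adjusted p = 0.0281, and adjusted p = 0.918 with an estimated correlation), and had an adjusted p = 0.419 without replicate 3 and 0.0901 without replicate 2. No gene passed in edgeR (smallest adjusted p = 1), with 247 genes at an unadjusted p under 0.05 (141 higher and 106 lower). That is 1.07% of those tested, fewer than unchanged genes would give by chance. DESeq2 called 2 genes, tob1b and si:dkey-84j12.1, both lower, and limma called 1, the latter, with library weights and on log2(FPKM + 1). The genes with the smallest p, which did not pass, were fut9b, prkg1a, mdm4, STUM and anxa3a on the higher side, from 1.00 to 2.86, and tob1b, ERRFI1 (1 of many), mych, csrnp1a and cdkn1a on the lower side. The value for tob1b was -1.11 ± 0.22. ERRFI1 (1 of many), at -1.51 ± 0.32, carries a name that marks several copies, between which the counting could divide reads, so its level is uncertain. The fall of cdkn1a, at -2.25 ± 0.51, passed when adjusted over the p53 targets list alone (edgeR adjusted p = 0.0427).

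RB1;TP53-cKO versus WT asks what joint loss of the E2F and p53 brakes does. Clock and immediate early genes were lower: 28 of 35 members of the circadian clock list, with a mean of -1.41, of which 11 fell when adjusted over the list alone (camera adjusted p = 3.81e-17, and adjusted p = 0.214 with an estimated correlation), and 23 of 31 of the immediate early and heat shock list, with a mean of -1.15, of which 8 fell by the same adjustment (camera adjusted p = 2.16e-11, and adjusted p = 0.163 with an estimated correlation). Examples are ciartb at -2.01 ± 0.40, cry2 at -1.51 ± 0.32, nr4a1 at -2.46 ± 0.59 and the Fos family gene fosab at -3.93 ± 1.1. Both falls rest on the single WT library, at 3.90 and 4.16 as mean log2(FPKM + 1) for these lists. The DNA replication and G1/S list was higher in 25 of 25 members, with a mean of 0.80 (camera adjusted p = 5.29e-06, and adjusted p = 0.554 with an estimated correlation), as was the mitosis list in 25 of 26, with a mean of 0.87 (camera adjusted p = 2.2e-05, and adjusted p = 0.605 with an estimated correlation). The thymidylate synthase gene tyms was at 1.12 ± 0.58, the mitotic cyclin gene ccnb2 at 1.33 ± 0.76 and its kinase cdk1 at 0.90 ± 0.52. The mitosis list stood at 3.95, 3.37 and 4.75 as mean log2(FPKM + 1) in replicates 1, 2 and 3 and at 3.42 in WT, and without replicate 3 its adjusted p = 0.0733. Matrix genes were higher, with 26 of 30 members of the list of fibroblasts, pericytes and matrix positive and a mean of 0.64 (camera adjusted p = 5.29e-06, and adjusted p = 0.232 with an estimated correlation), including the collagen gene col1a1a at 0.88 ± 0.22 and col12a1a at 1.06 ± 0.29. All 17 neutrophil genes were higher, with a mean of 1.40 (camera adjusted p = 6.45e-05, and adjusted p = 0.509 with an estimated correlation), with the collagenase gene mmp13a at 2.93 ± 1.00. The neutrophils list took 0.107% of the counts in replicate 2, the library highest in pancreatic enzymes, against 0.0136% and 0.0237% in replicates 1 and 3 and 0.0171% in WT.

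In the same comparison, the p53-activated genes cdkn1a, at -2.61 ± 0.51, and bbc3, which promotes cell death, at -1.26 ± 0.31, fell when adjusted over the p53 targets list alone, while the list had 13 members higher and 9 lower, with a negative mean and a median of 0.18, and was not called (camera adjusted p = 0.414). Neither fall followed the TP53 labels across the groups. In NF1-KO, whose label names no TP53 loss, cdkn1a was at -2.25 ± 0.51 against the single WT library. The level of bbc3 was 2.13 ± 0.0904 FPKM in NF1-KO and 2.29 ± 0.478 FPKM in NF1;TP53-cKO. No gene passed in edgeR (smallest adjusted p = 0.859), with 895 genes at an unadjusted p under 0.05 (504 higher and 391 lower), and 1455 without RB1;TP53-cKO replicate 2. With all libraries that is 3.89% of those tested, fewer than unchanged genes would give by chance. DESeq2 called 20 genes (6 higher and 14 lower), limma 0 with library weights and 1 on log2(FPKM + 1). Among the genes that met the rule for named genes, the lowest unadjusted p belonged to tob1b, at -1.51 ± 0.22. The stress genes chac1 (ENSDARG00000070426, chromosome 20, 28367802 to 28370372), an enzyme that breaks down glutathione, and gadd45ba, were at -1.57 ± 0.28 and -2.62 ± 0.47 and did not pass. On the higher side, prkg1a was at 1.83 ± 0.37 and and1 at 1.92 ± 0.39, and these did not pass either.

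NF1;TP53-cKO versus WT asks what loss of NF1 does together with loss of TP53. Protein synthesis and respiration genes moved apart. Of the ribosomal proteins list 81 of 82 members were higher, with a median of 0.79 (camera adjusted p = 4.09e-21, and adjusted p = 0.562 with an estimated correlation), among them rpl15 at 0.99 ± 0.27 and rpl8 at 1.17 ± 0.32. All 13 mitochondrially encoded genes were lower, with a mean of -0.85, and 8 fell when adjusted over the list alone (camera adjusted p = 4.69e-08, and adjusted p = 0.562 with an estimated correlation). The complex I genes mt-nd4l and mt-nd3 were at -0.99 ± 0.21 and -1.11 ± 0.27. The mitochondrial share of the counts was 2.81% and 3.26% in replicates 1 and 2, 5.92% in replicate 3 and 6.91% in WT. Pan-neuronal genes were lower in 28 of 28 cases, with a mean of -1.22 (camera adjusted p = 3.21e-13, and adjusted p = 0.562 with an estimated correlation), including the neurofilament genes nefmb at -1.18 ± 0.29 and nefla at -1.66 ± 0.47. The Notch and Hedgehog outputs list was higher in 22 of 23 members, with a mean of 1.11 (camera adjusted p = 1.16e-05, and adjusted p = 0.562 with an estimated correlation), including hhip and ptch2, which bind Hedgehog ligands, at 0.98 ± 0.31 and 1.60 ± 0.56. The mesenchymal glioma orthologs list was higher in 28 of 31 members, with a mean of 0.76 (camera adjusted p = 2.81e-06, and adjusted p = 0.516 with an estimated correlation), including timp2b, a metalloprotease inhibitor, at 2.76 ± 0.70 and snai1b, a factor of epithelial to mesenchymal transition, at 2.88 ± 0.95. The mitosis list was higher in 26 of 26 members, with a mean of 1.21 (camera adjusted p = 6.25e-08, and adjusted p = 0.562 with an estimated correlation). As mean log2(FPKM + 1) in replicates 1, 2 and 3, the mitosis list stood at 4.70, 4.76 and 3.46 against 3.42 in WT, and the Notch and Hedgehog outputs list at 4.02, 4.26 and 3.11 against 3.03.

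Replicates 1 and 2 of this group were among the 3 libraries that lay apart, and without those 3 the comparison with WT sets 1 library against 1, with the spread taken from the other groups. Camera at the preset correlation then made 17 list calls, of which 10 were among the 19 made with all libraries and 1 had the opposite direction. The mitosis list (adjusted p = 0.488) and the Notch and Hedgehog outputs (adjusted p = 0.244) were among those lost. No gene passed in edgeR for NF1;TP53-cKO versus WT (smallest adjusted p = 0.595), with 1328 genes at an unadjusted p under 0.05 (859 higher and 469 lower, 5.78% of those tested). DESeq2 called 13 genes (9 higher and 4 lower), limma 5183 with library weights and 1 on log2(FPKM + 1). The unadjusted count was 6577 without replicate 3, 511 without replicate 1 and 574 without replicate 2. Of the genes with the smallest p, which did not pass, the keratin gene krt18 was at 1.99 ± 0.43 and nocta (ENSDARG00000077726, chromosome 14, 47040711 to 47054844), a clock-controlled gene, at -2.0 ± 0.46. The collagenase gene mmp13a, at 4.56 ± 1.09, rose when adjusted over the neutrophils list alone (edgeR adjusted p = 0.0437).

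RB1;TP53-cKO versus NF1-KO contrasts 2 sets of lost tumor suppressors. The list of fibroblasts, pericytes and matrix was higher in RB1;TP53-cKO in 24 of 30 members, with a mean of 0.27 (camera adjusted p = 0.000118, and adjusted p = 0.475 with an estimated correlation). As mean log2(FPKM + 1), it stood at 4.49, 4.93 and 4.22 in RB1;TP53-cKO replicates 1, 2 and 3 and at 4.05 to 4.60 in NF1-KO. Replicates 1 and 3 thus lay within the range of NF1-KO. As a share of the counts, the list took 0.991%, 1.04% and 0.971% against 0.651% to 0.833%, without overlap. The actinodin gene and1 (ENSDARG00000088514, chromosome 24, 26134462 to 26138318), whose product builds the fibrils of fin folds, was at 37.6 ± 4.00 FPKM in NF1-KO and 111.4 ± 16.5 FPKM in RB1;TP53-cKO (n = 3 each), with a log2 fold change of 1.61 ± 0.25. Its relative and3 was at 1.77 ± 0.37, and col1a1a (ENSDARG00000012405, chromosome 3, 23090499 to 23108910) at 0.60 ± 0.15, and none of these genes passed. Of the mesenchymal glioma orthologs 26 of 31 were higher, with a median of 0.53 (camera adjusted p = 1.91e-08, and adjusted p = 0.195 with an estimated correlation), including fn1a at 0.89 ± 0.25 and the gelatinase gene mmp2 at 0.65 ± 0.20. The DNA replication and G1/S list was higher in 24 of 25 members, with a mean of 0.51 (camera adjusted p = 9.71e-07, and adjusted p = 0.532 with an estimated correlation). So was the mitosis list in 26 of 26, with a mean of 0.67 (camera adjusted p = 7.59e-08, and adjusted p = 0.53 with an estimated correlation), but without replicate 3 of the double knockout its adjusted p = 0.354. The list of neurons, pan, was lower in 28 of 28 members, with a mean of -0.53 (camera adjusted p = 1.91e-08, and adjusted p = 0.475 with an estimated correlation), and the circadian clock list in 33 of 35, with a mean of -0.61 (camera adjusted p = 6.77e-07, and adjusted p = 0.475 with an estimated correlation). As mean log2(FPKM + 1), the circadian clock list stood at 2.65, 3.08 and 2.01 in replicates 1, 2 and 3 of the double knockout and at 3.05 to 3.13 in NF1-KO, and the list of neurons at 4.93, 4.84 and 3.89 against 4.98 to 5.28, so replicate 3 lay lowest in both. The immediate early and heat shock list was not called between these groups, with 15 members higher and 16 lower (camera adjusted p = 0.423). No gene passed in edgeR (smallest adjusted p = 0.973), with 479 at an unadjusted p under 0.05 (312 higher and 167 lower). That is 2.08% of those tested, fewer than unchanged genes would give by chance. DESeq2 called 4, namely and1, ctslb (of which the table has 2 entries) and si:dkey-269i1.3 higher and si:ch211-266c8.1 lower, of which the last 3 were chosen after their values were seen, and limma called 0 by either route. The calls of ctslb and si:dkey-269i1.3 rest on replicate 3 of the double knockout, 1 of the libraries that lay apart, with 8.87 and 11.4 FPKM for the entries of ctslb and 2.84 FPKM for si:dkey-269i1.3, against at most 0.0567 FPKM in its replicates 1 and 2. The unadjusted count was 1408 without RB1;TP53-cKO replicate 2, 318 without its replicate 3, and 222 and 306 without replicates 1 and 2 of NF1-KO.

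NF1;TP53-cKO versus NF1-KO asks what loss of TP53 adds to loss of NF1. The labels name the NF1 loss cKO in the former and KO in the latter, so this comparison mixes TP53 loss with that difference. It gave the most genes at an unadjusted p under 0.05 of the 7 comparisons, 2826 (1839 higher and 987 lower, 12.3% of those tested). Members of lists that rose or fell are counted in this paragraph as adjusted over the list alone. Of 82 ribosomal proteins 70 rose, with a median of 0.71 (camera adjusted p = 3.6e-28, and adjusted p = 0.357 with an estimated correlation). Of 13 mitochondrially encoded genes 10 fell, with a mean of -0.79 (camera adjusted p = 2.68e-09, and adjusted p = 0.357 with an estimated correlation), such as mt-nd2, from 3302 to 1585 FPKM, at -0.98 ± 0.17. Of 31 genes of the immediate early and heat shock list 13 rose, with a mean of 1.52 (camera adjusted p = 2.56e-10, and adjusted p = 0.125 with an estimated correlation). They include the chaperone genes hsp70l, at 5.37 ± 1.05, and hsp70.1, at 6.20 ± 1.12, the latter one of several hsp70 genes, between which the counting could divide reads, and so uncertain in level. The spread of hsp70.1 within the group was wide, at 133.7 and 140.7 FPKM in replicates 1 and 2 and 4.92 FPKM in replicate 3. Of 23 Notch and Hedgehog outputs 5 rose, with a mean of 1.15 (camera adjusted p = 2.56e-10, and adjusted p = 0.367 with an estimated correlation), including ptch2 at 1.49 ± 0.36 and the Hedgehog effector gli1 at 1.65 ± 0.44. Of 31 mesenchymal glioma orthologs 6 rose, with a mean of 0.57 (camera adjusted p = 8.74e-07, and adjusted p = 0.222 with an estimated correlation), including serpine1, an inhibitor of plasminogen activation, at 2.53 ± 0.50, and cebpb, a factor linked to mesenchymal glioma, at 1.51 ± 0.30. The level of cebpb was 16.9 ± 4.64 FPKM in NF1-KO and 45.6 ± 6.56 FPKM in NF1;TP53-cKO, near the 48.3 FPKM of the single WT library. That of serpine1 was 2.96 ± 0.479 and 16.3 ± 4.61 FPKM, against 6.92 FPKM in WT. Of 28 pan-neuronal genes 3 fell, with a mean of -0.95 (camera adjusted p = 2.56e-10, and adjusted p = 0.357 with an estimated correlation), including nefla at -1.46 ± 0.37. Of the p53 targets, the p53-activated genes sesn2, at 1.29 ± 0.33, and ccng1, at 0.95 ± 0.26, rose and tigara, which lowers glycolytic flux, fell, at -1.26 ± 0.36, while camera did not call the list (adjusted p = 0.0564). Replicates 1 and 2, which lay apart, carried much of the mitochondrial, neuronal and Notch and Hedgehog differences: the mitochondrial share was 2.81%, 3.26% and 5.92% in replicates 1, 2 and 3 against 6.01% to 6.46% in NF1-KO, and the list of neurons stood at 3.60, 3.73 and 4.87 against 4.98 to 5.28. The Notch and Hedgehog outputs list stood at 4.02, 4.26 and 3.11 in these libraries and at 2.49 to 3.38 in NF1-KO, so replicate 3 lay within the range of NF1-KO.

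The wound- and growth-responsive transcription factor gene klf6a (ENSDARG00000029072, chromosome 24, 4109697 to 4117128) had the smallest p on the higher side, at 7.66 ± 1.25 FPKM in NF1-KO and 22.1 ± 0.840 FPKM in NF1;TP53-cKO (n = 3 each) and a log2 fold change of 1.62 ± 0.23. It did not pass over all genes, where edgeR called 0 (smallest adjusted p = 0.401). DESeq2 called 315 genes (248 higher and 67 lower), limma with library weights 12942, and limma on log2(FPKM + 1) 0. The count in edgeR rested on replicate 3 of the double knockout, without which 3181 genes passed (1355 higher and 1826 lower). The unadjusted count was 8215 without it, 962 and 994 without replicates 1 and 2 of its group, and 1233 and 1607 without replicates 1 and 3 of NF1-KO. Without the 3 libraries that lay apart, which leaves replicate 3 alone in the double knockout, camera at the preset correlation made 20 list calls, of which 12 were among those made with all libraries and 3 had the opposite direction, namely the DNA replication and G1/S (E2F-regulated) list, the retina and pineal list and the lens list.

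NF1;TP53-cKO versus RB1;TP53-cKO asks how NF1 loss differs from RB1 loss when TP53 is lost in both. The immediate early and heat shock list was higher in NF1;TP53-cKO in 28 of 31 members, with a mean of 1.64, and 13 rose when adjusted over the list alone, as are all counts of members in this paragraph (camera adjusted p = 6.16e-19, and adjusted p = 0.0361 with an estimated correlation). Of the 20 calls that camera made here, this one held with an estimated correlation. The stress factor atf3 was at 1.89 ± 0.37 and hsp70.1 at 5.72 ± 1.09. The heat shock list, added after the data were seen, stood at 6.17 and 6.12 as mean log2(FPKM + 1) in NF1;TP53-cKO replicates 1 and 2, at 4.13 in replicate 3 and at 3.58 to 4.13 in the other groups. Of 25 hypoxia and glycolysis genes 8 rose, with a mean of 0.72 (camera adjusted p = 3.01e-08, and adjusted p = 0.162 with an estimated correlation), including egln3, an oxygen sensor gene, at 4.05 ± 0.70 and ddit4 at 2.45 ± 0.48. The levels of egln3 were 26.5 and 24.4 FPKM in replicates 1 and 2, 5.52 FPKM in replicate 3 and at most 1.92 FPKM in RB1;TP53-cKO. As mean log2(FPKM + 1), the hypoxia and glycolysis list stood at 4.50 to 4.67 in NF1;TP53-cKO and at 3.76 to 4.33 in RB1;TP53-cKO. The single WT library stood at 4.72, so NF1;TP53-cKO did not lie above WT. Ribosomal proteins were higher in 80 of 82 cases, with a mean of 0.64, and 58 rose (camera adjusted p = 7.32e-36, and adjusted p = 0.432 with an estimated correlation). Mitochondrially encoded genes were lower in 12 of 13 cases, and 5 fell (camera adjusted p = 6.15e-05, and adjusted p = 0.588 with an estimated correlation). The mitochondrial share was 2.81% and 3.26% in NF1;TP53-cKO replicates 1 and 2, which lay apart, but 5.92% in replicate 3, above the 4.52% to 5.40% of the other group. As mean log2(FPKM + 1), the mitochondrial list stood at 10.67 in replicate 3, within the 10.65 to 10.87 of RB1;TP53-cKO. The Ras-MAPK feedback and outputs list was higher in 19 of 23 members, with a mean of 0.50 (camera adjusted p = 0.000126, and adjusted p = 0.231 with an estimated correlation). Its member fosl1a, a Fos family gene, rose, at 3.93 ± 0.82. As mean log2(FPKM + 1), the Ras-MAPK list stood at 3.48, 3.36 and 3.36 in NF1;TP53-cKO and at 2.99 to 3.22 in RB1;TP53-cKO. It stood at 3.33 in the single WT library and at 3.03 to 3.09 in NF1-KO, so it did not follow the NF1 labels across the groups. Cholesterol synthesis genes were lower in 20 of 22 cases, with a mean of -1.43 (camera adjusted p = 0.000135, and adjusted p = 0.666 with an estimated correlation), but the cholesterol synthesis list had an adjusted p = 0.835 without RB1;TP53-cKO replicate 2 and 0.0947 without NF1;TP53-cKO replicate 3.

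Between the double knockouts, the autophagy gene map1lc3cl (ENSDARG00000075727, chromosome 14, 46419007 to 46435486) had the smallest p, with 3.24 ± 0.837 FPKM in RB1;TP53-cKO and 12.3 ± 0.873 FPKM in NF1;TP53-cKO (n = 3 each), and 5.81 FPKM in WT. Its log2 fold change was 1.97 ± 0.24 (edgeR adjusted p = 0.343), and all 3 libraries of the one group lay above all 3 of the other, as the rule for named genes requires. The stress phosphatase subunit gene ppp1r15a was at 1.86 ± 0.29 and the endoplasmic reticulum chaperone gene dnajb11 at -0.71 ± 0.15, and neither passed. No gene passed in edgeR, with 1801 at an unadjusted p under 0.05 (1042 higher and 759 lower, 7.84% of those tested). DESeq2 called 190 genes (154 higher and 36 lower), limma 7477 with library weights and 0 on log2(FPKM + 1). Without NF1;TP53-cKO replicate 3, 105 genes passed in edgeR (94 higher and 11 lower). The unadjusted count was 5692 without that library, 929 and 779 without replicates 1 and 2 of its group, and 2698 without RB1;TP53-cKO replicate 3. The number of list calls ran from 12, without NF1;TP53-cKO replicate 1, to 26, without RB1;TP53-cKO replicate 3, and was 13 without its replicate 2. Without the 3 libraries that lay apart it was 11, of which 7 were among the 20 and 2 had the opposite direction.

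The F test asks for any difference among the mutant groups. In edgeR 0 genes passed (smallest adjusted p = 0.474), 1638 reached an unadjusted p under 0.05, which is 7.13% of those tested, and DESeq2 called 245. Without NF1;TP53-cKO replicate 3, 220 genes passed. The unadjusted count was 6202 without that library, 690 and 625 without replicates 1 and 2 of its group, 866 without NF1-KO replicate 1, and 1144 to 2240 without any other library. The comparisons with WT share 1 control library, which cannot be split. Across the 22984 genes, which are not independent replicates, the fold changes against WT correlated at 0.831 for NF1-KO and RB1;TP53-cKO, at 0.532 for NF1-KO and NF1;TP53-cKO and at 0.683 for both cKO groups. Simulated groups with no change, sharing 1 control, gave a mean of 0.810, 0.805 and 0.808 over 20 simulations. The covariances were 0.829, 0.617 and 0.985, against simulated means of 1.12, 1.11 and 1.11. At an unadjusted p under 0.05, these pairs shared 104, 92 and 250 higher genes, where independent lists would share 3.09, 5.27 and 18.8 and the simulated groups shared 367, 361 and 367 on average. They shared 84, 41 and 113 lower genes, against 1.8, 2.16 and 7.98 by chance and 122, 120 and 121 in the simulations. The correlation of NF1-KO with RB1;TP53-cKO lay above the highest of the simulations (0.817), whereas the covariances of all pairs lay below the simulated means. The numbers of shared genes decide nothing for the pairs with NF1-KO, whose 141 higher and 106 lower genes are fewer than the simulated groups shared. In every pair the simulated groups shared more genes on average than were observed. A shared control can thus give such an excess over independent lists without any change in common. The simulations gave larger covariances and more shared genes than these data, so they do not match them. They do not decide how much of the overlap comes from the control. No gene passed at an adjusted p under 0.1 in more than 1 of these comparisons.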

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

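The number of genes that edgeR called, 0 in every comparison, stayed at 0 with DESeq2 size factors, no filter, a mean of at least 2 FPKM, limma on log2(FPKM + 0.1), a minimum absolute log2 fold change of 1, which gives no value for the F test, and the 2 compared groups alone, which was run for the comparisons between mutant groups. It also stayed at 0 with the replicate number as a block, although the numbers do not pair the samples. DESeq2 called 7 genes in the mutants versus WT, then 2 in NF1-KO, 20 in RB1;TP53-cKO and 13 in NF1;TP53-cKO versus WT, 4 and 315 in these double knockouts versus NF1-KO, 190 between them, and 245 by the F test. Library weights called 29, 1, 0 and 5183 versus WT in the same order, 0 and 12942 versus NF1-KO, 7477 between the double knockouts and 12264 by the F test. They gave NF1;TP53-cKO replicate 3 a weight of 0.204 and replicate 2 one of 3.5. The cause of the difference between tools was not tested beyond these weights. Quantile normalization called 1 gene in the mutants, NF1-KO and RB1;TP53-cKO versus WT, and limma on log2(FPKM + 1), chosen after seeing the data, called 1 in each of the 4 comparisons with WT. That gene was always si:dkey-84j12.1.

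Leaving out 1 mutant library gave 0 to 3181 genes in NF1;TP53-cKO versus NF1-KO, 0 to 105 between the double knockouts and 0 to 220 by the F test, each time with the high end without NF1;TP53-cKO replicate 3, and 0 elsewhere. Leaving out the 3 libraries that lay apart, chosen after seeing the data, leaves replicate 3 of NF1;TP53-cKO alone in its group, with the spread taken from the other groups. It called 2 genes versus NF1-KO, pcdh1a4 and tgm2l, which rest on that library (tgm2l at 52.8 FPKM in it and 5.75 and 5.77 FPKM in replicates 1 and 2), and the same 2 by the F test, and leaving out the 2 libraries high in pancreatic enzymes, chosen after seeing the data too, called 0. The camera calls on lists at the preset correlation numbered 21 for the mutants versus WT, then 10, 21 and 19 for the single genotypes versus WT, 23 and 20 versus NF1-KO and 20 between the double knockouts. With an estimated correlation they numbered 0, 1, 0, 0, 0, 0 and 1. Leaving out 1 library gave 12 to 26 list calls between the double knockouts, and leaving out the 3 gave 11, of which 7 were kept and 2 had reversed. With the 3 left out, 3 of 20 list calls had reversed in NF1;TP53-cKO versus NF1-KO (12 kept) and 1 of 17 in NF1;TP53-cKO versus WT (10 kept).

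For the named genes, 16320 of 16986 alternative values kept both call and direction, 571 passed where edgeR did not (376 of them with library weights, 92 with DESeq2 and 103 without NF1;TP53-cKO replicate 3), 94 moved and 1 reversed. The reversed value was that of rpe65a, a gene of the visual cycle, between the double knockouts, at 1.28 ± 1.33 in edgeR and -2.87 with library weights (adjusted p = 0.0118). In the case of tp53, NF1;TP53-cKO versus WT had an adjusted p of 0.00973 with library weights.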

Other observations

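The tests in these paragraphs were chosen after the results were seen, except the levels of heart and kidney markers and the splits of the samples. Some gene groups were not described with the comparisons. Cholesterol synthesis genes stood at 3.90 and 4.26 as mean log2(FPKM + 1) in NF1-KO replicate 3 and RB1;TP53-cKO replicate 2, against 2.03 to 2.74 in the other libraries, and genes of liver and intestine stood at 6.29 and 6.51 in them, against 2.66 to 4.50. The erythrocytes list was higher in NF1;TP53-cKO than in WT in 17 of 17 members, with a mean of 1.99 (camera adjusted p = 6.95e-07, and adjusted p = 0.562 with an estimated correlation), including alas2, which makes heme, at 1.72 ± 0.76. It stood at 4.64 and 4.55 as mean log2(FPKM + 1) in replicates 1 and 2, which lay apart, at 3.30 in replicate 3 and at 2.88 in WT, and RB1;TP53-cKO replicate 3, which lay apart too, was at 4.11. The interferon response, the radial glia and astroglia, and the pituitary lists were called in no comparison.

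Genes of muscle and skin were present in all 10 libraries, although the labels name brain. Tissue next to the brain carried along from 90-day-old fish would bring adult rather than embryonic globins, and embryonic and larval globins took at least 0.068% of the counts in every library. This does not decide, because adult globins had at most 6 counts in a library and their symbols overlap, so the table does not tell the kinds of globin apart, but such tissue would cover muscle and skin at most, and not the exocrine pancreas list at up to 0.98% of the counts, liver and intestine, or he1a at up to 263.5 FPKM. Whole embryos or larvae would bring heart and kidney: the kidney markers averaged 3.09 to 12.6 FPKM, above the value of 1 FPKM set before these markers were looked up, and the heart markers 9.13 to 11.9 FPKM, below the 10 FPKM set for them in 5 of the 10 libraries. The kidney mean rested largely on cdh17, at 11.8 to 83.3 FPKM, while no other kidney marker exceeded 7.62 FPKM. The highest values of cdh17 were in RB1;TP53-cKO replicate 2 and NF1-KO replicate 3, the libraries high in pancreatic enzymes. For muscle and skin both explanations stay open and cannot be told apart with these values.

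RB1;TP53-cKO replicate 3 and NF1;TP53-cKO replicates 1 and 2 lay apart from the other 7 libraries. An earlier developmental stage would lower genes of late-maturing cells, and in 5 of 5 lists (photoreceptors, myelin, glutamatergic neurons, GABAergic neurons and cerebellum) these libraries held the 3 lowest values, but such genes had prompted this explanation and cannot support it. Genotype as the whole cause would place the 3 in 1 group, and 1 of them, RB1;TP53-cKO replicate 3, lay nearest a library of another label, which excludes genotype only if the labels hold. With the labels of RB1;TP53-cKO replicate 3 and NF1;TP53-cKO replicate 3 exchanged, the F test gave 8107 genes at an unadjusted p under 0.05 against 1638 as labelled, but this follows from where these libraries lie, and 6 of 8 values of the targeted genes, not all, lay nearer the other group. Stage, genotype and exchanged labels cannot be told apart with these libraries.

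The immediate early and heat shock list was higher in NF1;TP53-cKO than in both other mutant groups, while the WT library, at 4.16 as mean log2(FPKM + 1), lay among those of NF1;TP53-cKO. NF1 loss alone, raising immediate early genes through Ras, would raise the list as much in NF1-KO. The list stood at 4.54, 4.48 and 3.99 in NF1;TP53-cKO replicates 1, 2 and 3 and at 2.92 to 3.53 in NF1-KO. The gap between the nearest libraries was 0.46, against SDs of 0.30 and 0.31. Replicates 1 and 2 would keep their labels if those of the 2 replicates 3 were exchanged. These values argue against NF1 loss alone as the whole cause for this mixed list. They do not test immediate early genes apart from chaperone genes. The neuronal activity and immediate early list stood at 2.90, 2.82 and 3.64 in NF1;TP53-cKO replicates 1, 2 and 3. In those of NF1-KO it stood at 2.44, 3.22 and 2.51, so the groups overlapped. The single WT library stood at 4.07, above every library of both groups, so this list showed no rise over WT in either. Since that rests on 1 WT library, NF1 loss alone is not excluded for immediate early genes. Heat or handling stress of some libraries would raise chaperone genes in part of the NF1;TP53-cKO group. The heat shock list stood over 1 (log2) above every library of the other groups in 2 of the 3 libraries, while replicate 3, at 4.13, was level with the highest of the others, but the chaperone genes had prompted this explanation. Heat or handling stays open and cannot be told apart from an effect of NF1 and TP53 loss together, which was not tested.

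The mutant libraries were split in other ways to see how often a split gives as many genes at an unadjusted p under 0.05, with the real split counted in. For the F test, 19 of 100 splits, the real one and 99 drawn from the other splits among 280, gave at least 1638 genes, so chance is not excluded. The highest other split gave 11437, which points to a structure of the samples. For the comparisons of 2 groups the 10 splits, the real one included, are too few to test. In RB1;TP53-cKO versus NF1-KO 5 of these gave at least the real 479 (highest other 4460), in NF1;TP53-cKO versus NF1-KO 3 gave at least the real 2826 (highest other 4149), and between the double knockouts 4 gave at least the real 1801 (highest other 8561).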
